A study of Rattus norvegicus with 7 samples.

How the data were processed

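The data were 7 arrays of rat liver total RNA, 4 from rats on a PFOS diet and 3 from rats on a control diet, with 1 rat per array and nothing pooled. Groups were taken from the sample titles, and replicate numbers only name the arrays. RNA had been hybridised from 4 rats per group, per the labels, and 1 control array was left out by the submitters after quality control. Per the file headers, the arrays were 1-colour Agilent miRNA arrays on 1 slide with 1 scan time, and spot intensity values were made by Feature Extraction 10.7.3.1. The intensity column used, the processed signal, is background-subtracted and spatially detrended but not normalized between arrays, per the file headers. The flags used (well above background, gene detected, outlier, saturated) were set by the same software. The deposited series value table holds log2 values that the authors normalized by cyclic lowess, per the labels. Set against the scanner files, each column followed the median over a miRNA's spots of the log2 median pixel signal, with no background subtracted (Pearson r across miRNAs of 0.9987 to 0.9999, miRNAs not being independent replicates). The column medians of the table were 5.50, 5.50, 5.48, 5.50, 5.51, 5.50 and 5.51, with no centring per miRNA, and its direction is that of signal. The settings of the authors' lowess are not given in the sources used here, and neither is their test. The array's own annotation is of another assembly than the gene table used here, so no coordinates are given, and GRCr8 served only for which genes neighbour each other.

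For the main values, spots of a probe were averaged on the linear scale over 13540 non-control spots and 1644 probes, leaving out spots with an outlier flag. The probes of a miRNA were summed. There were 2 probes for 514 miRNAs, 4 for 133, 3 for 27 and 1 for 3. Arrays were scaled to a common 75th percentile over the miRNAs detected on all arrays. Values below the 1st percentile of detected values (12.1) were set to it, and log2 was taken. Cyclic loess followed (limma, method pairs, span 0.7, 3 iterations), with weight on the miRNAs detected on all arrays. A miRNA was detected on an array where over 50% of the kept spots of at least 1 probe were well above background. Tested were the miRNAs detected on all 3 control arrays or on at least 3 PFOS arrays.

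Groups were compared per miRNA with lmFit and eBayes (limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 6.51 degrees of freedom per miRNA, of which 1.51 came from the moderation. Lists of miRNAs were tested with camera (preset correlation of 0.01, and an estimated one) and fry (directional and mixed), adjusted over the 14 lists with at least 2 tested members. Arm ratios were fitted per array with limma. Array measures were compared by exact two-sided permutation over 35 splits, which cannot give a p below 0.0286. Files were read with data.table (version 1.17.8) and jsonlite 2.0.0, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

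The lists, the tests, the rule for named miRNAs and the alternatives were fixed before the data were examined. The rule named up to 15 miRNAs per direction past the threshold, the 10 of smallest p if fewer than 10 passed, up to 4 examples per list by smallest p, and the 5 brightest, which gave 29. The mixed p of fry was read after the other results. List examples were further limited to an unadjusted p under 0.05, a limit set after the values were seen. The bound for a miRNA not well above background in 1 group was computed from normalized log2 means. Alternatives changed the normalization, background, signal column, summary, detection filter, floor, moderation, slide row and threshold, and left out each array in turn. The planned mean pixel signal was not in the columns, so normexp (offset 50) ran on the median signal. Another 3 alternatives were chosen after seeing the data, namely scaling by the labelling spike-in and 2 remakes of the value table.

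The normalization and fit were tested on simulated data drawn from the real means and spreads of the 175 tested miRNAs, with 30 changed in each of 20 draws. For the comparison of PFOS with control, 43.5% of changes of 0.5 on the log2 scale were recovered, 78.0% of changes of 1 and 87.5% of changes of 2. Of the calls, 6.90% were unchanged miRNAs. Noise was drawn independently for each miRNA, unlike in the real arrays. A draw gave 22.45 calls on average, which eases the adjusted threshold, against 0 calls in the real comparison. The recovery rates are therefore not the power behind those 0 calls.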

Results

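Liver miRNA was profiled in adult male Sprague-Dawley rats fed a control diet or a diet containing potassium perfluorooctanesulfonate (PFOS), a persistent fluorinated surfactant, at 50 mg/kg of diet for 28 days. Total RNA was labelled with Cy3 and hybridised to Agilent rat miRNA arrays, 1 rat per array. The series holds 4 PFOS arrays and 3 control arrays, after its submitters left out a control array that did not meet their quality criteria. Each array carried probes for 677 rat miRNAs, of which 175 were detected widely enough to be tested, 123 were detected on all 7 arrays and 458 on none. Precision was limited by the number of arrays. The question that the comparison addressed was which hepatic miRNAs differ after dietary PFOS in a study of thyroid hormone homeostasis. Names are given as on the array, without the species prefix.

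The 3 largest positive differences among the tested miRNAs all belonged to the miR-200 family, miRNAs that are abundant in epithelial cells and target the Zeb transcription factors. The normalised signal of miR-200b averaged 204 in PFOS livers and 58.3 in control livers, a log2 fold change of 1.81 (SE 0.48, n = 4 and 3 arrays). For miR-200a the means were 125 and 42.2, a log2 fold change of 1.57 (SE 0.37). The signal of miR-429 was well above background on all 4 PFOS arrays and on no control array, and was at least 2.03-fold higher in PFOS livers. That bound sets the mean of the PFOS arrays against the higher of each control array's lowest detected signal and its own reading. For each of these 3 miRNAs the 4 PFOS values lay above the 3 control values, and both probes of each were higher in PFOS. Within the first slide row the log2 differences were 2.58 for miR-200b and 2.12 for miR-200a, and within the second row 1.59 and 1.41. Control replicate 1 was the only control array of the first row. It had the lowest signal of both, 26.5 for miR-200b and 24.4 for miR-200a. The genes of these 3 miRNAs are neighbours on chromosome 5 in the GRCr8 annotation.

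None of the 3 passed on its own over all tested miRNAs, each with an adjusted p of 0.131 in limma. As a list fixed beforehand, with 3 tested of 9 on the array, the miR-200 family was higher in PFOS livers with a median log2 fold change of 1.57, also with miR-429 at its bound (camera with a preset correlation, adjusted p = 0.00269 over 14 lists). The call was lost with an estimated correlation (adjusted p = 0.665), and fry gave an adjusted p of 0.121. All 3 members passed when p was adjusted over the list alone, against 0 over all tested miRNAs. The list is not independent evidence of its direction, because the study is remembered to have reported this family. The call was also lost under cyclic loess with equal weights, where the median was 1.15 and the smallest limma adjusted p of any miRNA was 0.9985. There the 458 miRNAs detected on no array had equal weight, and miR-20a, with main signals of 311 to 391, came out at -4.05. That loss is therefore not read as evidence on the family. With untested members included the list still passed (camera adjusted p = 0.000125). Its median was then -0.15, the value of a miRNA held at the floor on every array. The median was 0.62 with normexp and 0.73 with the unsubtracted median signal. With slide row as a block all 3 members passed in limma. The PFOS arrays also had 2.23-fold more labelling spike-in signal than the control arrays.

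**Figure D1:**
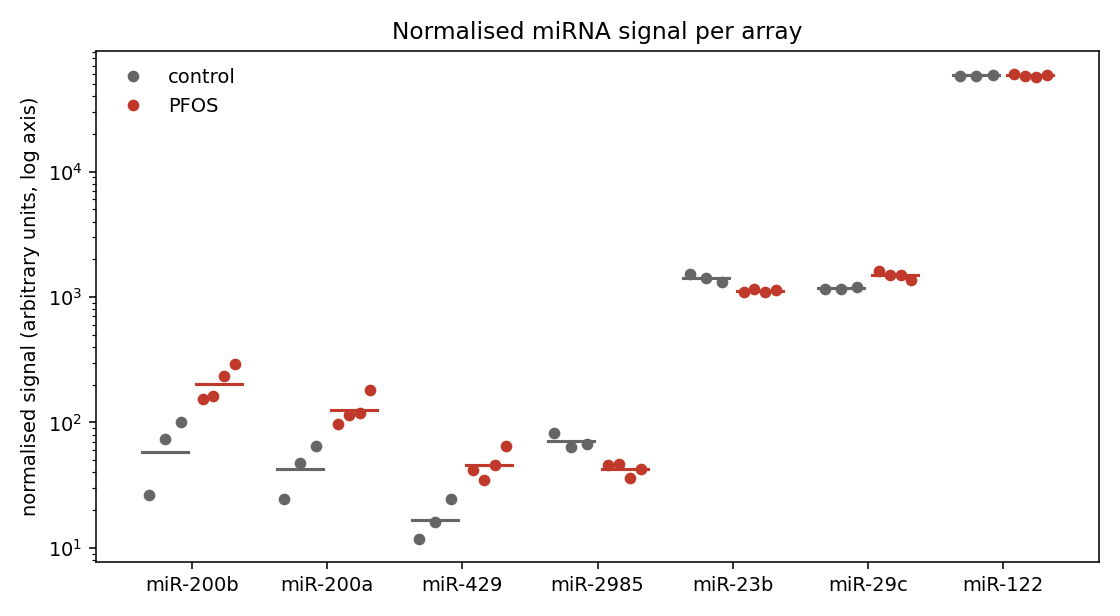
Normalised signal of 7 miRNAs on each array, on a log axis in arbitrary units, with 1 point per array and a line at the mean of the log2 values of 4 PFOS and 3 control arrays. The PFOS points of miR-200b, miR-200a and miR-429 lie above all control points, those of miR-2985 and miR-23b lie below them, and miR-122 overlaps.

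Over all tested miRNAs, limma found 0 higher and 0 lower in PFOS livers at an adjusted p under 0.05, and the smallest adjusted p was 0.131. At an unadjusted p under 0.05 there were 15 higher and 19 lower miRNAs, 34 in all, where 8.75 would be expected by chance. The groups did not overlap for 17 miRNAs in each direction, 34 in all, where 10 are expected by chance (5.71% of the tested miRNAs). Both expected counts are averages over groupings, and a given grouping can lie far from them. The split that moves PFOS replicate 1 to the control arrays gave 33 miRNAs at an unadjusted p under 0.05. Of the 19 lower miRNAs at that p, 9 were among the dimmest 44 tested. The differences beyond 2-fold were 3 positive ones, in the miR-200 family, and 4 negative ones, in miR-466d, miR-672, miR-32* and miR-466b, whose groups overlapped. The last 4 were named after their values were seen, and without PFOS replicate 4 none was beyond 2-fold, with log2 fold changes of -0.96 for miR-466d, -0.61 for miR-672, -0.60 for miR-32* and -0.62 for miR-466b. The median log2 fold change was -0.02 and the median standard error 0.14. Other scalings gave other splits of higher and lower calls, 3 and 0 under 75th percentile scaling over all miRNAs and 0 and 8 under labelling spike-in scaling, which was chosen after seeing the data. With normexp background correction the split was 6 and 16, and 5 of the lower ones had a positive fitted value in the main processing.

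The 10 miRNAs with the smallest p also included 2 brighter ones, miR-29c and miR-23b. The groups did not overlap for these 2, nor for miR-20b-5p, miR-2985, miR-3085 and miR-3573-3p, and choosing by smallest p favours such separation. The signal of miR-29c, a miRNA that targets collagen transcripts, averaged 1491 in PFOS and 1173 in control livers, a log2 fold change of 0.35 (SE 0.08). That of miR-23b averaged 1121 and 1421, a log2 fold change of -0.34 (SE 0.07). The log2 fold change was 0.26 (SE 0.07) for miR-20b-5p. It was -0.73 (SE 0.14) for miR-2985, -0.90 (SE 0.24) for miR-3085 and -0.60 (SE 0.15) for miR-3573-3p, which are dim, with PFOS means of 42.5, 24.6 and 21.6. Of the control arrays, 2 measured miR-3085 above background and 1 measured miR-3573-3p. None of these values passed, all with an adjusted p of 0.131 in limma. With slide row as a block, miR-2985 passed (-0.78, limma adjusted p = 0.0259, and above 0.05 for the other miRNAs of this paragraph). For miR-350, well above background on 3 PFOS arrays and no control array, no fold is given, since its control reading was the higher one. A miRNA held at the floor on every array came out at -0.15 after normalization, and the dimmest 44 of the tested miRNAs had a median log2 fold change of -0.19.

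**Figure D2:**
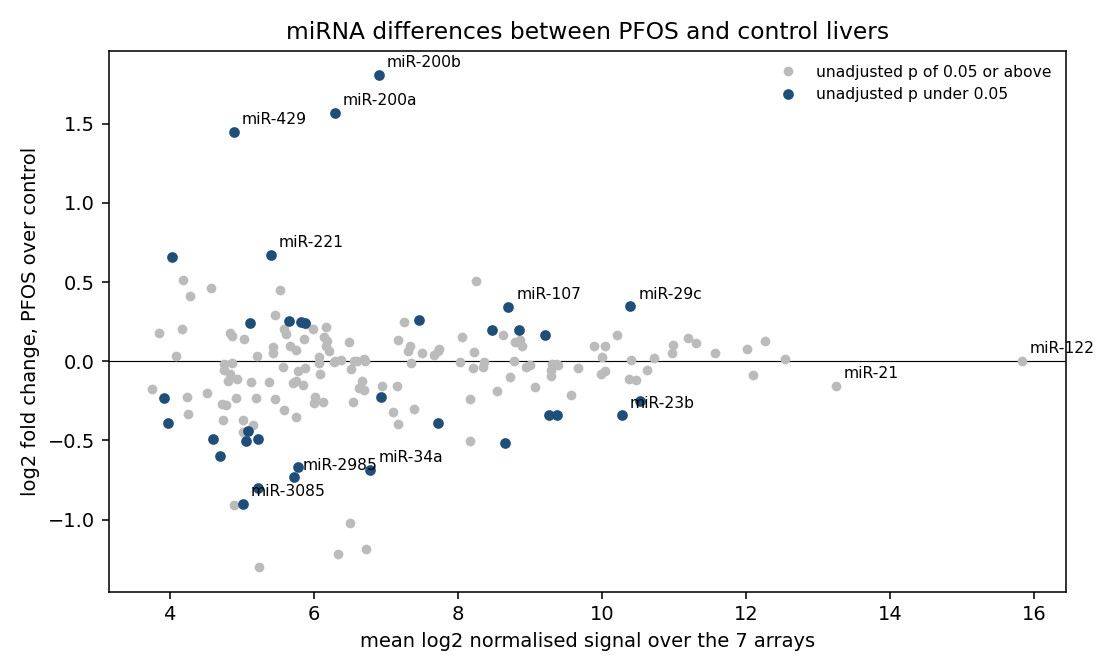
Log2 fold change of PFOS over control against the mean log2 normalised signal for the 175 tested miRNAs, 1 point each, with dark points at an unadjusted p under 0.05. The 3 points above a log2 fold change of 1 are miR-200b, miR-200a and miR-429, and none of the points passed after adjustment.

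The hepatocyte-enriched list had 10 tested members, 6 with a positive and 4 with a negative fold change, and a median of 0.01 (camera adjusted p = 0.928), or -0.24 in the deposited value table. Its members ran from -0.25 to 0.45, and fry's mixed test, which asks whether members differ in either direction, passed for this list (adjusted p = 5.6e-05 over 14 lists, unadjusted 4.0e-06). Of the 35 splits of the arrays, 5 with the real one included gave this list a mixed p under 0.05, and the smallest in another split than the real one was 8.0e-05 unadjusted. That test, read after the other results, also passed for the lipid (0.00174), miR-17-92 (0.00329), miR-30 (0.00502) and miR-23/24/27 (0.0310) lists, 5 in all. These are not separate results, since the lipid list shares miR-122 and miR-122* with the hepatocyte-enriched list. It also shares miR-27a and miR-27b with the miR-23/24/27 list. The count was 0 under 75th percentile scaling over all miRNAs, labelling spike-in scaling and cyclic loess with equal weights. The most abundant of the hepatocyte-enriched miRNAs, miR-122, averaged 58654 in PFOS and 58485 in control livers, a log2 fold change of 0.00 (SE 0.06). Its direction turned with the normalization, at -0.11 under 75th percentile scaling without loess and -0.67 in the deposited value table. It was far brighter than the next miRNA, miR-21, at 8554 to 11064, and entered the loess with full weight. The curve at that end may follow miR-122 itself, which would pull its difference and spread towards 0. The value of 0.00 is therefore no evidence of an unchanged level. The log2 fold change was 0.01 (SE 0.08) for miR-22, -0.09 (SE 0.07) for miR-192 and 0.20 (SE 0.07) for miR-101a. The other arm of the miR-122 precursor, miR-122*, gave -0.25 (SE 0.08). Of the other brightest miRNAs, miR-21 gave -0.15 (SE 0.11) and let-7f 0.13 (SE 0.08).

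The miR-23/24/27 clusters, from which miR-23b and miR-27b are transcribed together, had 5 of 5 tested members with a negative fold change and a median of -0.21 (camera adjusted p = 0.0946). With an estimated correlation the adjusted p was 0.665. Within it, miR-23b and miR-27b (-0.34, SE 0.10) passed when adjusted over the list alone, and 0 passed over all tested miRNAs. The median turned to 0.08 under 75th percentile scaling over all miRNAs, where the median of all tested miRNAs moved to 0.25. The list passed as lower under quantile normalization (-0.21, camera adjusted p = 0.0402) and in the deposited value table (-0.39, adjusted p = 0.00165), among others. The miR-17-92 and paralogous clusters, often raised in proliferating cells, had 7 positive and 2 negative members of 9 and a median of 0.09 (camera adjusted p = 0.0947, and adjusted p = 0.665 with an estimated correlation). Their examples were miR-20b-5p, miR-17-5p at 0.24 (SE 0.07), miR-93 at 0.25 (SE 0.09) and miR-20a at 0.19 (SE 0.07), and the first 2 passed when adjusted over the list alone. The miR-29 family had a median of 0.14 over 4 members (camera adjusted p = 0.213, and 0.724 with an estimated correlation), and miR-29c passed when adjusted over the list alone. The miR-30 family had a median of 0.10 over 7 members (camera adjusted p = 0.128, and 0.665 with an estimated correlation), with miR-30a at 0.17 (SE 0.07). Under labelling spike-in scaling, where the median of all tested miRNAs was -0.43, the medians of these positive lists were -0.31 for miR-17-92, -0.22 for miR-29 and -0.31 for miR-30. Those of miR-29 and miR-30 were also negative under cyclic loess with equal weights and in the deposited value table. The miR-29 list passed as higher in PFOS livers without PFOS replicate 4 (median 0.19, camera adjusted p = 0.0171) and in 2 remakes of that table (0.16, adjusted p = 0.0355, and 0.15, adjusted p = 0.0105). The miR-17-92 list passed as higher under 75th percentile scaling over miRNAs detected on all arrays (0.16, camera adjusted p = 0.0469), normexp (0.06, adjusted p = 0.0490) and without control replicate 3 (0.13, adjusted p = 0.0494). The miR-30 list passed as higher under normexp (0.05, camera adjusted p = 0.0470). All of these list calls used the preset correlation. The let-7 family had a median of 0.06 and a mean of -0.07 over 10 members (adjusted p = 0.714), with let-7b* at -0.67 (SE 0.27), which was above background on 3 PFOS and 2 control arrays.

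Lists of other cell types did not pass, and the signs of their medians turned with the scaling. Stellate cell and fibroblast miRNAs had a median of -0.03 and a mean of 0.06 over 8 members (camera adjusted p = 0.928), with miR-221 at 0.67 (SE 0.21), above background on 2 of 3 control arrays, and miR-152 at 0.25 (SE 0.10). Its member miR-145 was well above background on 3 PFOS arrays and no control array, and has no fold for the reason given for miR-350. Leukocyte and Kupffer cell miRNAs had a median of -0.02 over 7 members (adjusted p = 0.928), with miR-223, a myeloid miRNA, at -0.23 (SE 0.09). The endothelial list, with both arms of miR-126, had a median of 0.01 (adjusted p = 0.928). The erythroid list, miR-451 and miR-144, had a median of -0.10 (adjusted p = 0.928), or 0.17 under 75th percentile scaling over all miRNAs. The neuronal list had a median of -0.01 and a camera direction of up (adjusted p = 0.983). The lipid and cholesterol metabolism list had a median of 0.00 and a mean of -0.04 over 11 members (adjusted p = 0.928), with miR-107 at 0.34 (SE 0.10). Of the Dlk1-Dio3 imprinted cluster, 3 of 70 miRNAs on the array were tested, with a median of -0.31 (adjusted p = 0.681), or -0.05 over the 2 tested without PFOS replicate 4. Another 5 lists had 1 tested member and no list test. Their log2 fold changes were -0.69 (SE 0.25) for miR-34a, a target of p53. For the other lists they were -0.91 (SE 0.63) for miR-206, 0.29 (SE 0.46) for miR-96, -0.23 (SE 0.18) for the hypoxia-induced miR-210 and -0.04 (SE 0.11) for miR-181a. Without PFOS replicate 4 the value of miR-96 turned to -0.10 (SE 0.26) and that of miR-206 was -0.64 (SE 0.60).

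The 2 arms of a precursor were compared within each array for 24 pairs. The ratio of miR-99a to miR-99a* was higher in PFOS livers by 0.47 on the log2 scale (SE 0.09, limma adjusted p = 0.0308), and the other 23 ratios did not pass. The log2 fold change was 0.02 for miR-99a and -0.44 for miR-99a*, which was well above background on 3 PFOS arrays and 1 control array. The next smallest adjusted p, 0.0653 in limma, was that of miR-29c over miR-29c*, for which no difference is given because miR-29c* was well above background on no control array. At an unadjusted p under 0.05 there were 5 ratios. Without PFOS replicate 1 the count was 1 ratio past the threshold, and without any other single array it was 0.

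More miRNAs were detected on the PFOS arrays, 181.8 ± 16.0 (SD, n = 4) against 149.3 ± 22.2 (SD, n = 3), a difference that did not pass an exact two-sided permutation test (p = 0.0857). PFOS arrays had from 161 to 200 detected miRNAs and control arrays from 131 to 174. On the first slide row the ratio of PFOS to control was 0.986 and on the second 1.40. Among the tested miRNAs, 10 were detected only on PFOS arrays, among them miR-429, miR-145 and miR-350, and 0 only on control arrays. The median unscaled signal of miRNAs detected on all arrays was 258 ± 46.2 (SD, n = 4) on PFOS and 149 ± 23.9 (SD, n = 3) on control arrays (exact two-sided permutation p = 0.0286, the smallest that 35 splits can give). Adjusted over 8 array measures this was 0.0762. The negative control spots differed little, with medians of 42.1 ± 2.58 (SD, n = 4) and 43.3 ± 2.28 (SD, n = 3), and no spot was saturated.

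**Figure D3:**
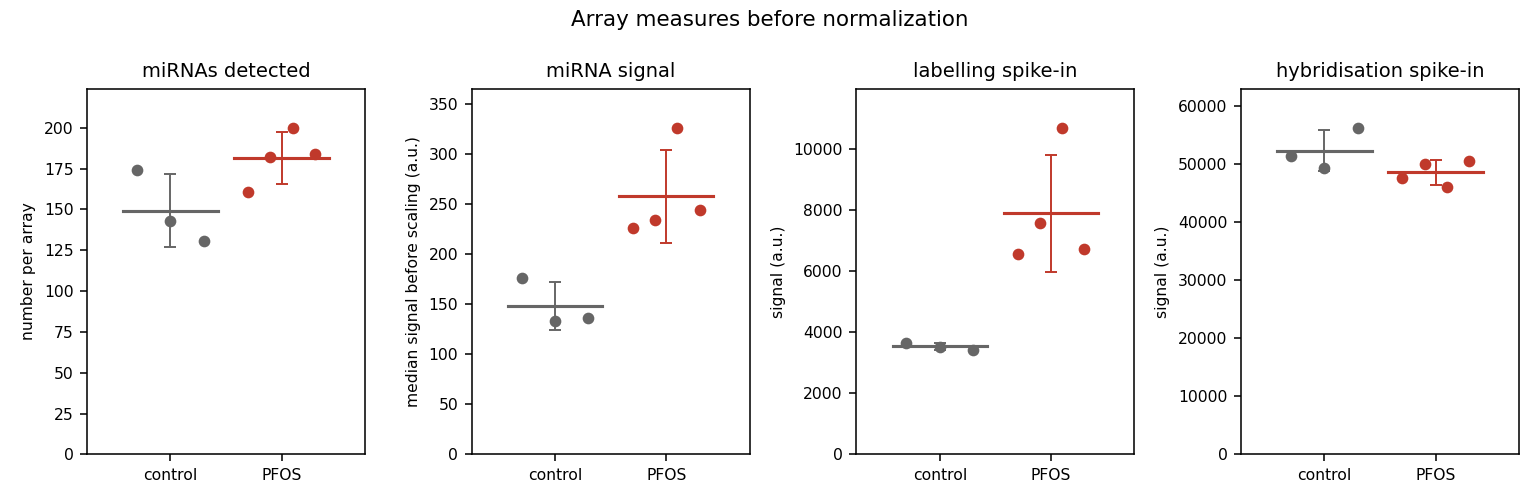
Detected miRNAs, median unscaled miRNA signal, labelling spike-in signal and hybridisation spike-in signal (arbitrary units) per array, with 1 point per array and a line and bar at the mean ± SD of 4 PFOS and 3 control arrays. The labelling spike-in lies between 6570 and 10686 on PFOS arrays and between 3431 and 3659 on control arrays, and the hybridisation spike-in overlaps.

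The deposited value table gave another set of calls. Fitted in the same way with limma, it had 0 higher and 9 lower miRNAs at an adjusted p under 0.05. They were miR-122 (log2 fold change -0.67, SE 0.12), miR-21 (-0.63), miR-23b (-0.58), miR-652* (-0.52), miR-27b (-0.50), miR-192 (-0.44), miR-122* (-0.43), miR-22 (-0.42) and miR-194 (-0.30). Under 75th percentile scaling of the scanner signals none of the 9 passed, and their median log2 fold change was -0.13. Before any normalization the 9 had a median log2 difference of 0.52, higher in PFOS. The PFOS arrays were brighter as a whole, by 1.74-fold in the median unscaled signal of miRNAs detected on all arrays. The 0.52 therefore shows no higher level of the 9 relative to other miRNAs. In the table miR-200b, miR-200a and miR-429 had a median of 0.63, on a scale from which no background was subtracted.

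**Figure D4:**
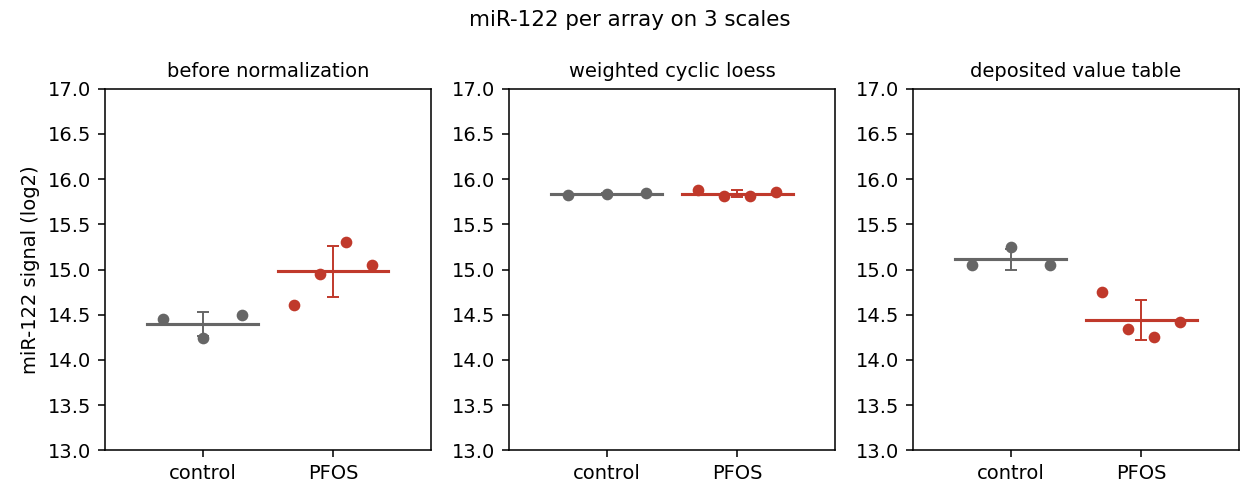
Log2 signal of miR-122 per array before normalization, after the weighted cyclic loess and in the deposited value table, with 1 point per array and a line and bar at the mean ± SD of 4 PFOS and 3 control arrays. PFOS arrays, which were brighter as a whole, lie above control arrays before normalization and below them in the table.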

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

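The tests by spike-ins, of the slide row, of epithelial cells, of the deposited table and of fry's mixed counts were chosen only after the results had been seen. Values of 33 measures on the 4 PFOS arrays were screened for an array far from the others, which chance gives for about 1 group in 20. For miR-350, PFOS replicate 4 read 16.4 and the other 3 PFOS arrays at most 13.4, a gap of 0.867 of the whole range, with all 4 near the floor.

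The labelling spike-in, which does not enter the main comparison of miRNAs, was 2.23-fold higher on PFOS arrays, 7887 ± 1919 (SD, n = 4) against 3534 ± 116 (SD, n = 3), with an exact permutation p of 0.0286, or 0.0762 adjusted over 8 measures. The ratio was 1.93 in the first slide row and 2.51 in the second. The hybridisation spike-in had a ratio of 0.929 (exact permutation p = 0.171), which argues against hybridisation, washing or scanning. More miRNA per total RNA in PFOS livers would raise miRNA signal over the labelling spike-in, but that ratio was 0.722 of the control value (exact permutation p = 0.0286). A higher labelling yield on the PFOS arrays would raise the spike-in, but alone it would leave the ratio of miRNA signal to spike-in unchanged. That ratio ran from 8.84% to 11.6% on PFOS arrays and from 12.3% to 15.4% on control arrays. Yield alone therefore does not account for these values, and what lowered the ratio was not tested. Whether a higher yield came with the diet group or with the order of handling is open.

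Array brightness and slide row were weighed for the higher miR-200b, miR-200a and miR-429 signals. After normalization, the 112 tested miRNAs of similar signal had a median log2 fold change of -0.0513 and a highest of 0.67, against 1.57 for the 3. The normalization itself holds that median near 0, and brightness separated the diet groups, so this comparison cannot decide on array brightness. The smallest of the 4 differences of miR-200b and miR-200a within slide rows, found in the second row, was 1.41, which argues against the row. In the first row the differences rest on control replicate 1 alone. A larger share of bile duct or other epithelial cells cannot be told apart from a change within hepatocytes, because miR-200c and miR-141, other members of the family, were well above background in 0 of 14 readings. The highest median shift of the 3 in any other split was 1.38, in the split of the 3 brightest from the 4 dimmest arrays. That split is the real one with PFOS replicate 1 moved to the control arrays. In 1 of the 35 splits of the arrays, the real one, the median shift of the 3 was as large as 1.57. That is the smallest share 35 splits can give, and the splits took no account of slide row, so chance is not excluded. The same 3 members were used in every split, and miR-429 was detected on PFOS arrays only. The family is also one the study is remembered to have reported, so the test is not independent. A change within hepatocytes and one in cell makeup stay open.

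The 9 miRNAs lower in PFOS in the deposited table may owe the size of their difference to the normalization between arrays. Their mean level before normalization and in the table ran in opposite order over the 7 arrays (Spearman rho = -0.929, exact permutation p = 0.00675, Pearson r = -0.910, exact permutation p = 0.00972, and r = -0.915 without the 2 arrays farthest from the median). The diet groups differ on both measures, so the relation is also the group difference turned round, and it was not tested within groups of 4 and 3 arrays. A remake with 1 loess pass gave the 9 a median of -0.26, and 3 passes gave -0.17, against -0.50 in the table. Lower levels of that size relative to other miRNAs would remain under 75th percentile scaling, where the median was -0.13. Its SE of 0.05 was taken over the 9 miRNAs, which are not independent, and leaves out the spread between rats. That SE therefore cannot exclude a lowering of the size in the table. A smaller lowering also stays open, with -0.15 in the main processing and, under spike-in scaling, -0.60 against -0.43 for all tested miRNAs.

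The real split called 0 miRNAs, which all 35 of the 35 splits reach by definition, so chance cannot be excluded for that count, and the highest other called 6. At an unadjusted p under 0.05 the real split gave 34 miRNAs, matched by 1 of 35 splits, the real one, and the highest other gave 33. That was again the split by array brightness, which is the real split with PFOS replicate 1 moved to the control arrays. The slide rows gave 7. For list calls, 16 of 35 splits gave at least the real 1, and the highest other gave 3, so chance is not excluded for that count. For lists past fry's mixed test, 1 of 35 splits, the real one, gave as many as 5, and the highest other gave 4. The mixed test was read after the other results, the margin is 1 list and splits were run under the main processing only, so this rank gives no independent exclusion of chance. For arm ratios 3 of 35 splits gave at least the real 1, and the highest other gave 2, so chance is not excluded there either.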

How the results depend on the processing

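Only the following alternatives were chosen after seeing the data, the labelling spike-in scaling and the 2 remakes of the value table. Signal over background limits the dim miRNAs, and the cause of each change below was not tested unless stated. No paired analysis was possible because the replicate numbers name arrays and pair none. Among the named miRNAs, direction and side of the threshold were kept in 518 combinations of miRNA and alternative, 37 passed the threshold newly in the same direction, and the sign turned in 47. With arrays left out, both were kept in 180 and the sign turned in 8. List shifts other than the miR-200 family moved by over 1 SD in 35 cases, and in 1 more with arrays left out.

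Counts of miRNAs past the threshold were 0 higher and 0 lower. They were 3 higher under 75th percentile scaling over all miRNAs, where the median of all moved to 0.25. Under normexp there were 6 higher and 16 lower, with the unsubtracted median signal 5 higher and 15 lower, and with Feature Extraction's total signal 1 higher. The lower calls under normexp and with the unsubtracted signal each included 5 miRNAs whose fitted value was positive in the main processing, miR-193*, miR-32, miR-339-3p, miR-674-3p and miR-7a-1*. With no filter there was 1 lower, with slide row as a block 3 higher and 1 lower (miR-2985), 9 lower in the deposited table, and under spike-in scaling 8 lower, where the median of all moved to -0.43. With any array left out the counts were 0 and 0, as with an adjusted p under 0.1. Lists higher in PFOS numbered 1, but 2 under 75th percentile scaling (also miR-17-92), 0 under equal-weight loess, 3 under normexp (also miR-17-92 and miR-30), 2 in both remakes (also miR-29) and 1 to 2 with arrays left out (2 without PFOS replicate 4, with miR-29, or control replicate 3, with miR-17-92). Lists lower numbered 0, but 1 (the miR-23/24/27 clusters) under quantile normalization, the brightest probe, the filter for all arrays, eBayes with a trend, with and without the robust option, the deposited table and both remakes, and 0 to 1 with arrays left out (1 without PFOS replicate 2, PFOS replicate 4 or control replicate 3). Arm ratios numbered 1, but 0 under quantile normalization, equal-weight loess, total signal and the mean of log2 over probes, 2 under both 75th percentile scalings, normexp and the unsubtracted signal, and 0 to 1 with arrays left out (1 only without PFOS replicate 1). Lists past fry's mixed test numbered 5, but 3 under quantile normalization and the remake with 1 pass, 2 in that with 3 passes, 8 under normexp, 9 with total signal and 0 under 75th percentile scaling over all miRNAs, equal-weight loess, no filter and spike-in scaling, and 4 to 7 with arrays left out. The miR-200 family shift of 1.57 ranged from 1.24 to 1.93 with arrays left out. It was 0.62 under normexp, 0.73 with the unsubtracted median signal, 0.63 in the deposited table, 0.63 and 0.62 in its remakes and 1.15 under equal-weight loess, where it did not pass, and -0.15 with no filter, where 6 members below background on all arrays set the median.

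Log2 fold changes turned as follows. Under equal-weight loess, where the smallest adjusted p of any miRNA was 0.9985 in limma, they were -2.20 for miR-29c, 0.36 for miR-3085, -4.05 for miR-20a, -0.70 for miR-30a, -0.63 for miR-122, -3.19 for miR-22 and -0.28 for let-7f. That setting moved miRNAs of steady signal such as miR-20a far from 0, so its values are not read as changes of direction. Under spike-in scaling they were -0.0104 for miR-29c, -0.13 for miR-20b-5p, -0.24 for miR-101a, -0.18 for miR-17-5p, -0.18 for miR-93, -0.24 for miR-20a, -0.26 for miR-30a, -0.17 for miR-152, -0.10 for miR-107, -0.58 for miR-122, -0.40 for miR-22 and -0.28 for let-7f, all with the median of all at -0.43. Under 75th percentile scaling over all miRNAs they were 0.0781 for miR-122*, 0.0424 for miR-223, 0.0881 for miR-21 and 0.20 for miR-192. In the deposited table they were -0.0135 for miR-101a, -0.00638 for miR-20a, -0.0738 for miR-30a, -0.67 for miR-122, -0.42 for miR-22 and -0.25 for let-7f. The remake with 1 pass gave -0.56 for miR-122, -0.18 for miR-22 and -6.0e-04 for let-7f, and that with 3 passes -0.0282 and -0.0390 for the first 2. The mean of log2 over probes gave -0.0110 for miR-22, and 75th percentile scaling -0.11 for miR-122. With arrays left out, the range was -0.0102 to 0.0105 for miR-122 and -0.0328 to 0.0543 for miR-22.

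For miR-429, miR-350 and miR-145, above background on no control array, the fitted log2 values are no folds, and a change of their sign shows no change of direction. The values whose sign differed from the main one were -0.16 for miR-429 and 0.47 for miR-145 under equal-weight loess, and 0.0101 for miR-350 and 0.12 for miR-145 under 75th percentile scaling over all miRNAs. They were 9.2e-05 and 0.0165 for these 2 in the deposited table, and 0.30 and 0.22 with the brightest probe. For miR-145 they were also 0.12 under quantile normalization, 0.0098 and 0.0311 in the remakes with 1 and 3 passes, and between -0.31 and 0.0673 with arrays left out, the highest without control replicate 3.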

Other observations

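The tests of the shared chromosome and of neighbours among miRNAs of similar signal were chosen only after the values had been seen. Of the 20 tested miRNAs with the largest spread within groups, 12 had their lowest signal on PFOS replicate 4. No chance value is given, since a very low array itself gives a large spread and several of the 12 share a family. They were miR-466b, miR-466b-1*, miR-466b-2*, miR-466c*, miR-466d, miR-672, miR-32*, miR-485*, miR-207, miR-764, miR-206 and miR-196c, with SDs of 0.74 to 1.47 on the log2 scale against a median of 0.19. The signal of miR-466b-1* was 532, 468, 272 and 75.7 on PFOS replicates 1 to 4, and 395, 260 and 306 on control replicates 1 to 3. For miR-32* it was 192, 115, 66.6 and 20.5, and 210, 203 and 112. The 12 go back to 10 gene names, 3 of them miR-466 names, and the genes matched to these names lie on 6 chromosomes in GRCr8, so transcription from 1 locus does not account for it. What else these miRNAs or their probes share was not tested.

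Neighbouring miRNA genes may change together after PFOS. Among 130 genes matched by name in GRCr8, for 151 tested names, 18 pairs of consecutive matched genes lay within 10000 bases of each other. Their log2 fold changes differed by 0.13 on average, against 0.41 for random pairs (one-sided permutation p = 5.0e-05 with 100000 resamples). Without the miR-200 family 16 pairs differed by 0.13, against 0.35 (p = 9.0e-05, permutation). With values permuted only among miRNAs of similar signal, the random difference was 0.39 and p was 5.0e-05. The members had the same sign in 16 pairs and opposite signs in 2, miR-362* with miR-500 (0.24 and -0.22) and miR-199a-3p with miR-214 (0.13 and -0.11). Differences ran from 0.00339, in miR-450a with miR-322 near no change, to 0.47, and miR-23b with miR-27b had -0.34 each. Pairs would also move together if rats differ in a cluster's transcription for reasons other than the diet, and this was not separated. The 18 pairs are only a part of all neighbours, since genes with numbered copies could go unmatched. Of the miR-17-92 cluster they held miR-19a with miR-20a (0.04 and 0.19). They left out miR-17-5p (0.24), miR-19b (-0.11) and miR-92a (-0.17). The p and the counts of signs therefore hold for the matched pairs alone.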
